A study of Mus musculus with 9 samples.

How the data were processed

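Polyadenylated RNA of wild-type mouse embryonic stem cells in embryoid body differentiation was measured in 9 libraries, 3 for each of the groups EBD2, EBD5 and EBD6. Per the labels' protocols, total RNA was extracted with Trizol, captured with oligo-dT beads and made into libraries with a KAPA RNA Hyperprep kit. The libraries were sequenced on HiSeq and NovaSeq instruments, and the labels do not say which library ran on which. Per the submitters' processing notes, cutadapt 1.18, STAR 2.7.10a, RSEM 1.3.30, edgeR 3.40.2, DESeq2 1.38.3 and the genome build mm10 were used, with no role or order given. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not have been told apart.

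The authors deposited expected counts per gene, that is, estimated read counts that need not be whole, which were not scaled to depth or length. Between 90.9% and 94.6% of the values per library were whole. A second table held the 3 EBD6 libraries with values identical to those of the first in all 54233 rows. The expected counts were rounded to whole numbers before any test. Of the rows, 54232 were Ensembl gene IDs and 1, named MR3, was not. MR3 names no gene of the annotation, took at most 0.0157% of a library's counts and was left out of library sizes and tests. Symbols, positions, GC content and length came from GENCODE release M21 of the same build, which held 54079 of the IDs (99.7%). Where several IDs shared a symbol, the ID with the most counts was used.

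Libraries of each group were compared by a chi-square test over genes with at least 20 counts in the pair. EBD2 replicates 1 and 2 (chi-square per gene 0.95) and EBD6 replicates 2 and 3 (1.01, p = 0.169 by the chi-square test of counts) agree within sampling noise, and each pair was summed and counted as 1 sample. The design fixed before the data were examined held 9 separate libraries. The change to 7 samples followed a rule on near-identical replicates, but it was made after the counts from 9 libraries had been seen, so both sets of counts are given. The pairs still differed in 40 and 44 genes, 9 of them mitochondrial in each pair. EBD5 replicates 1 and 3 differed in fewer genes (37) but beyond sampling noise over all genes (chi-square per gene 1.21, p = 5.85e-66 by the chi-square test of counts), and were kept as 2 samples. Counting them as 1 sample was tried as well. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels use the same replicate numbers in each group and do not say that they mark a shared culture.

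Genes were kept by edgeR's filterByExpr, which left 16168 of 54232 for testing. Counts were scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with all 3 groups in one fit, no covariates, 4 residual degrees of freedom and a common biological coefficient of variation of 6.7%. P-values were adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. CPM values use the TMM-scaled library sizes, and a summed pair enters the mean ± SD as 1 sample. The SE of a log2 fold change was taken as its size divided by the square root of F. Where a group had no count, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with its 95% counting interval. Such intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries held 5454268 to 11704761 counts, which set the depth.

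A set of 40 gene lists with 469 genes, 15 of them in more than 1 list, was fixed before the data were examined. The 39 with at least 4 tested members were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01 between genes and adjusted over the 117 tests, with fry and with camera at an estimated correlation beside it. Also fixed before the data were examined were the groups, the tests, the alternatives marked so and the rule for named genes. By that rule a comparison may name up to 4 members per list and direction with the largest significant change, the 8 largest rises and 8 largest falls over all genes with at least 10 CPM and non-overlapping replicates, and 30 anchor genes. The text names a subset of the genes so allowed, 77 genes in 101 gene and comparison pairs, picked after their values were seen. Beside these it names 3 genes that held much of an RNA class, chosen after their values were seen.

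The alternatives fixed before the data were examined were DESeq2 size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, only the groups compared, the replicate number as a block, a test against a fold of 1.5, EBD6 from the second table, an estimated correlation for lists, and leaving out each library in turn. Chosen after seeing the data were 9 separate libraries, EBD5 replicates 1 and 3 as 1 sample, the removal of medians in 10 bins of GC content by 10 bins of length, protein-coding genes without mitochondrial, ribosomal protein and replication histone genes, and EBD6 libraries thinned to the depth of replicate 1. With the bins removed, camera ran on log2 CPM without voom weights and without TMM factors, so that setting changed these as well.

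The steps were tested on simulated data drawn from the real means and library sizes, in which 67, 67 and 66 of 16168 genes changed by a fold of 1.5, 2 and 4. For EBD5 against EBD2, edgeR recovered 43.3%, 68.7% and 89.4% of them and 8.8% of its calls were false. For EBD6 against EBD5 it recovered 58.2%, 79.1% and 90.9% with 11.6% false, and for EBD6 against EBD2 49.3%, 79.1% and 92.4% with 12% false. The false shares exceed the nominal 5%. Few genes changed in the simulation, around means pooled over the groups, whereas most tested genes were called in each real comparison. The shares recovered and false therefore need not hold for the real calls, and scaling when most genes change was not tested. In the same simulations camera called the changed list in every comparison with the preset and the estimated correlation, and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, so this cannot show whether the preset correlation is adequate for the real lists. A planted trend with GC content gave 6792, 6896 and 6515 false calls in the 3 comparisons, which the bins reduced to 10, 25 and 14. This trend was planted in groups without changed genes. It cannot show whether the bins also remove real changes that go with GC content.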

Results

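Wild-type mouse embryonic stem cells were differentiated as embryoid bodies, aggregates in which pluripotent cells give rise to derivatives of the germ layers, and their polyadenylated RNA was sequenced. The series set out to follow gene expression through this differentiation. The labels name 3 groups, EBD2, EBD5 and EBD6, with 3 libraries each, and do not say what the number in the name stands for. EBD2 replicates 1 to 3 held 5658402, 5884870 and 5613463 counts. EBD5 replicates 1 to 3 held 5850799, 6376807 and 5646106 counts, and EBD6 replicates 1 to 3 held 5454268, 10447491 and 11704761 counts. EBD2 replicates 1 and 2 (chi-square per gene 0.95) and EBD6 replicates 2 and 3 (1.01) did not differ beyond the sampling noise by a chi-square test of counts. The other pairs of those groups differed by 2.23 to 4.31, and the pairs of EBD5 by 1.21 to 3.4. Each of these pairs was therefore counted as 1 sample, which left 2 EBD2, 3 EBD5 and 2 EBD6 samples. Levels are counts scaled to library size, in CPM, as mean ± SD with n = 2 for EBD2, n = 3 for EBD5 and n = 2 for EBD6, with the standard error (SE) beside log2 fold changes. Over the 9 libraries the first principal component held 51.1% of the variance and the second 41.0%, and the libraries of each group lay together.

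The EBD5 libraries differed from those of EBD2 and EBD6 in the classes of RNA they held. Nuclear ribosomal RNA genes took 0.773 ± 0.0433% of counts in EBD5, against 0.0196 ± 0.00150% in EBD2 and 0.0228 ± 0.00115% in EBD6. Nearly all of this came from 1 of the class's genes, CT010467.1, which was looked up after the values had been seen and took 0.773%, 0.0195% and 0.0226%. Mitochondrial ribosomal RNA genes took 0.536 ± 0.0139% in EBD5, 0.0149 ± 0.00177% in EBD2 and 0.00862 ± 0.00349% in EBD6. Processed pseudogenes, which are retrotransposed copies of genes, took 1.13 ± 0.0134% in EBD5, 0.307 ± 0.0565% in EBD2 and 0.201 ± 0.00292% in EBD6. Long intergenic non-coding genes took 1.502 ± 0.1426% in EBD5, 0.6425 ± 0.01375% in EBD2 and 0.5056 ± 0.01346% in EBD6. MicroRNA genes went the other way, at 0.000502 ± 6.75e-05% in EBD5 against 0.00929 ± 0.00115% in EBD2 and 0.00873 ± 0.000399% in EBD6. These too came largely from a few genes, among them Gm22133 and Mir6236, also looked up afterwards, with 29.7 and 27.0 CPM in EBD2. Each of these shares in every EBD5 library lay outside the range of the other libraries. For EBD5 against either other group alone, 3 libraries against 3, an exact permutation test cannot give a two-sided p below 0.1. With the near-identical pairs counted as 1 sample, chance alone separates EBD5 from either other group in 20% of cases. Across 13746 protein-coding genes, GC content was correlated with the log2 fold change of EBD5 against EBD2 (Spearman rho = -0.37) and of EBD6 against EBD5 (0.56), and less with that of EBD6 against EBD2 (0.17). These correlations are across genes, which are not independent replicates.

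**Figure D1:**
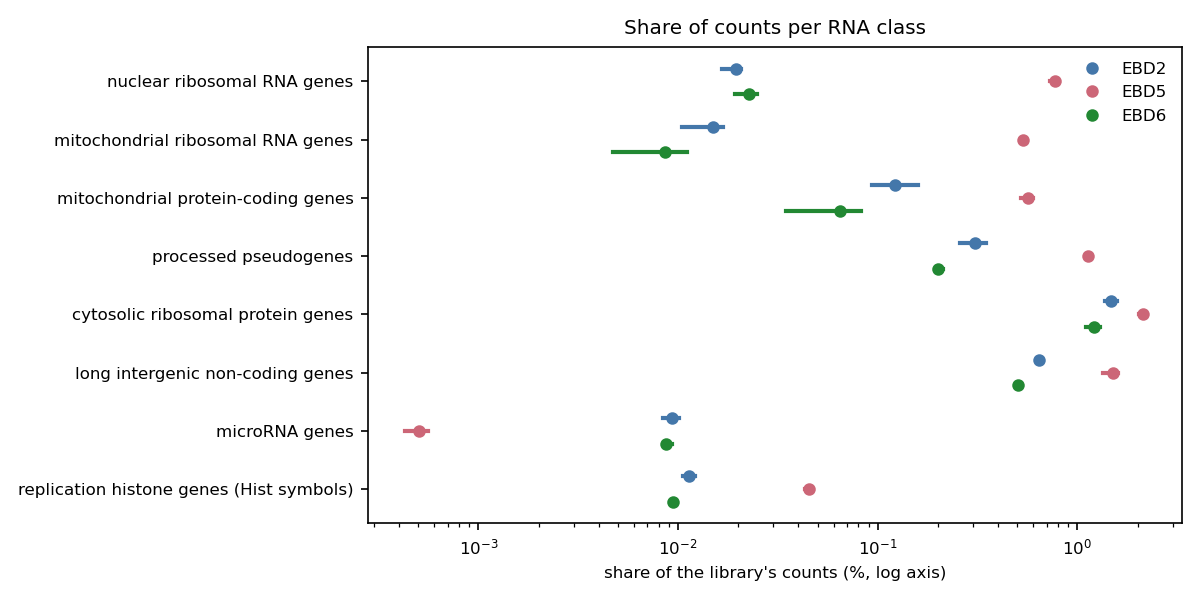
Share of each library's counts (percent, log axis) taken by 8 classes of RNA. Points are group means over 2 EBD2, 3 EBD5 and 2 EBD6 samples and bars run from the lowest to the highest library; nuclear ribosomal RNA genes stood at 0.773% in EBD5 and at 0.0196% and 0.0228% in EBD2 and EBD6.

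**Figure D2:**
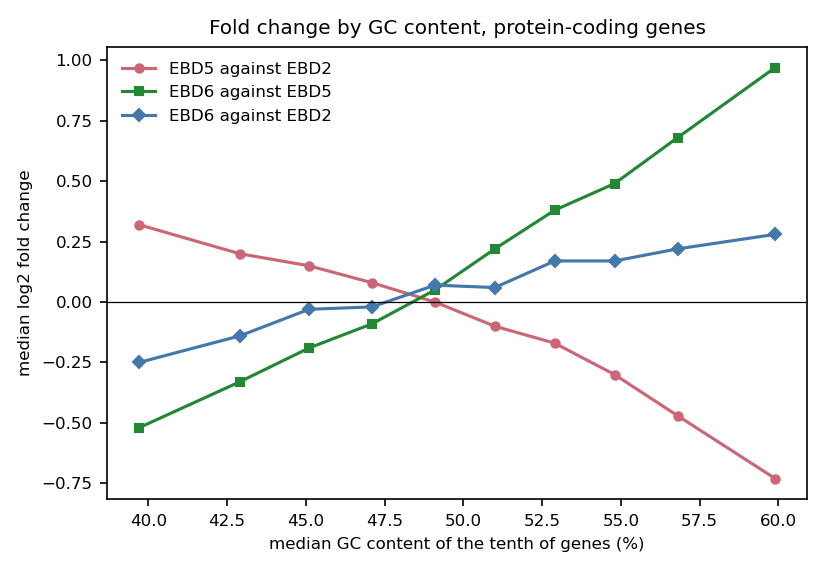
Median log2 fold change of protein-coding genes in 10 bins of GC content (x axis, percent) for the 3 comparisons. In EBD6 against EBD5 the median went from -0.52 in the bin with the lowest GC content to 0.97 in the highest, and in EBD5 against EBD2 from 0.32 to -0.73.

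Between EBD2 and EBD5, genes of the visceral endoderm, the extraembryonic layer that takes up and secretes nutrients around the early embryo, were higher in EBD5. Of 14 tested genes on the visceral endoderm list 13 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.04e-06; adjusted p = 0.213 with an estimated correlation). Cubn, which encodes the endocytic receptor cubilin (ENSMUSG00000026726, chromosome 2, 13276338 to 13491813, minus strand, mm10), rose from 4.06 ± 0.0177 to 1125 ± 12.2 CPM, a fold of 276 (log2 8.11 ± 0.11 SE; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 7.64e-12). Apoa1, an apolipoprotein gene, rose 359-fold to 106 ± 6.13 CPM (log2 8.49, or 10.04 without EBD2 replicate 2). Afp, the gene of the fetal serum protein alpha-fetoprotein (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907, plus strand), rose 154-fold to 71.6 ± 1.98 CPM. Ttr, which encodes the thyroid hormone carrier transthyretin, had 3 counts in EBD2 and 1269 in EBD5, a ratio of 445 (95% counting interval 152 to 2160); without EBD2 replicate 3, EBD2 had 1 count. Apoa4 had no count in EBD2 and was at least 248-fold higher in EBD5, taking 3 counts over the group as the limit.

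All 11 tested genes of the primitive and parietal endoderm list rose, also when adjusted over the list alone (camera adjusted p = 1.01e-06; adjusted p = 0.213 with an estimated correlation). They included Dab2, an endocytic adaptor gene (17.4 ± 1.61 to 826 ± 34.1 CPM, 48.3-fold), Lama1, which encodes a laminin chain of the basement membrane (40.9-fold, to 259 ± 7.25 CPM), and the transcription factor genes Sox7 (105-fold), Gata6 (18.4-fold) and Gata4 (8.94-fold). Among transcription factor genes on the primitive streak and definitive endoderm lists, Lhx1 rose from 0.472 ± 0.0795 to 134 ± 10.7 CPM (log2 8.17 ± 0.18 SE) and Foxa2 from 0.519 ± 0.263 to 34.5 ± 2.98 CPM (log2 6.21 ± 0.23 SE). Sox17 rose from 0.653 ± 0.571 to 16.2 ± 1.11 CPM (log2 4.94, or 5.94 without EBD2 replicate 3) and Eomes from 27.7 ± 3.48 to 132 ± 2.31 CPM. Of 7 definitive endoderm genes 6 rose and 1 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0615; adjusted p = 0.543 with an estimated correlation). The primitive streak list had 8 of 10 members higher and 1 lower, with the same counts adjusted over the list alone, and missed the threshold (camera adjusted p = 0.0521; adjusted p = 0.579 with an estimated correlation). Among secreted antagonists, Cer1 had 1 count in EBD2 and 400 in EBD5 (ratio 420, 95% counting interval 75 to 16600), and Dkk1 had none in EBD2 and was at least 218-fold higher in EBD5. Cyp26a1, whose product breaks down retinoic acid, rose 258-fold to 91.1 ± 3.004 CPM. The lists that hold Dkk1 (Wnt response, 3 of 9 rose and 5 fell; camera adjusted p = 0.518) and Cyp26a1 (retinoic acid response, 3 of 7 rose and 4 fell; camera adjusted p = 0.894) did not pass, with the same counts adjusted over the list alone. Over all tested genes, the transcription factor genes Tfec, at least 499-fold higher in EBD5, and Maf, with 1 count in EBD2 and 1010 in EBD5 (ratio 1060, 95% counting interval 190 to 42000), were among the largest rises. The EBD2 count of Cer1 was in replicate 3 and that of Maf in replicate 2, without which EBD2 had 0. Of 11 epithelial junction genes 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0429; adjusted p = 0.523 with an estimated correlation). Without EBD5 replicate 3 this list missed the threshold by camera (adjusted p = 0.0505). The simple-epithelium keratin gene Krt8 of that list rose 7.94-fold to 148 CPM (log2 2.99 ± 0.10 SE).

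Genes of the two-cell-like state, a rare state of stem cell cultures that resembles the early cleavage embryo, were lower in EBD5. All 6 tested members fell, also when adjusted over the list alone (camera adjusted p = 0.00703; adjusted p = 0.275 with an estimated correlation). Zscan4a had 120 counts in EBD2 and 1 in EBD5 (ratio 114, 95% counting interval 20.1 to 4550; 0 counts without EBD5 replicate 3), and Usp17lc was at least 14-fold lower in EBD5. Members of these families are near-identical copies, so their single values are uncertain. Of 14 core pluripotency genes 8 fell and 3 rose, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0615; adjusted p = 0.558 with an estimated correlation). The pluripotency factor gene Sox2 fell from 353 ± 25.9 to 160 ± 12.1 CPM (log2 -1.14 ± 0.09 SE), and the DNA methyltransferase gene Dnmt3a from 502 ± 3.29 to 208 ± 8.26 CPM. Lefty2, a feedback inhibitor of Nodal signalling, fell from 176 ± 7.57 to 70.0 ± 1.87 CPM. Pou5f1, the gene of the pluripotency factor Oct4 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, plus strand), stood at 266 ± 46.8 and 231 ± 5.32 CPM and did not pass (edgeR with Benjamini-Hochberg, log2 -0.19, adjusted p = 0.0952). Without a filter on low counts it passed (edgeR with Benjamini-Hochberg, log2 -0.20, adjusted p = 0.0112), and in the other alternatives the adjusted p was 0.0526 to 1. Zfp42 did not pass either, at 101 ± 6.25 and 101 ± 22.6 CPM (edgeR with Benjamini-Hochberg, adjusted p = 0.917). Nanog was slightly higher in EBD5 (185 ± 11.21 and 231 ± 4.82 CPM, log2 0.32 ± 0.09 SE; edgeR with Benjamini-Hochberg, adjusted p = 0.00585). That call ended when tested against a fold of 1.5. Neuronal beta-tubulin Tubb3 fell from 31.7 ± 0.235 to 5.02 ± 1.08 CPM. Other lists with these genes did not pass either, with the same counts adjusted over the list alone. They were those of formative and primed epiblast (6 of 11 fell and 2 rose; camera adjusted p = 0.253), DNA methylation (5 of 8 and 2; 0.134), Nodal response (4 of 7 and 2; 0.249) and neuroectoderm (7 of 12 and 3; 0.251).

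All 7 tested mitochondrially encoded genes rose in EBD5, also when adjusted over the list alone (camera adjusted p = 0.00121; adjusted p = 0.531 with an estimated correlation). mt-Co1, a subunit of cytochrome c oxidase, went from 321 ± 44.1 to 2287 ± 271 CPM. Of 22 ribosomal protein genes 18 rose and none fell, or 18 and 1 adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.54 with an estimated correlation), with Rps4x at 169 ± 18.0 and 651 ± 41.4 CPM. Of 11 replication histone genes, whose messenger RNAs end without a poly(A) tail, 9 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.362 with an estimated correlation). Hist1h1e went from 2.13 ± 0.519 to 41.4 ± 3.06 CPM. Values of single ribosomal protein and histone genes are uncertain because they share sequence with pseudogenes and copies. These 3 lists moved with the share of nuclear ribosomal RNA, which was 39.4 times as high in EBD5 as in EBD2 and came nearly all from CT010467.1, and with that of processed pseudogenes, which was 3.68 times as high.

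In total 5641 genes were higher and 5678 lower in EBD5 than in EBD2 among 16168 tested (edgeR quasi-likelihood, Benjamini-Hochberg). Tested against a fold of 1.5 the counts were 2972 and 2634. Of the 39 lists tested 7 passed camera, 6 higher and 1 lower, and none passed with an estimated correlation (smallest adjusted p = 0.213; 3 lists had an unadjusted p under 0.05). The test fry, which asks only whether a list's genes move on balance in a direction, gave 30. With the 9 libraries as separate samples 5911 genes were higher and 5786 lower, and 11078 of the 11319 calls were shared. With the medians of bins of GC content and length removed, 9116 of the calls kept their direction and 167 turned. With these bins the log2 change was -1.89 for Tubb3 and 2.12 for mt-Co1, against -2.65 and 2.83.

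Between EBD5 and EBD6, genes of the lateral plate and extraembryonic mesoderm, trophoblast and ectoderm were higher in EBD6 by camera with its preset correlation. None of these lists passed with an estimated correlation (camera adjusted p = 0.284 for mesoderm, 0.275 for trophoblast, 0.275 for surface ectoderm and 0.42 for neuroectoderm), and 1 mesoderm and 1 neuroectoderm gene fell. Hand1, a transcription factor gene of the extraembryonic and lateral mesoderm and trophoblast (ENSMUSG00000037335, chromosome 11, 57828705 to 57832818, minus strand, mm10), rose from 4.30 ± 0.551 to 67.0 ± 2.20 CPM, a fold of 15.6 (log2 3.96 ± 0.12 SE; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 3.75e-09). Of 9 tested members of its mesoderm list 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0163; adjusted p = 0.284 with an estimated correlation). Among endothelial and blood progenitor genes, Cdh5, which encodes the endothelial cadherin, rose from 2.04 ± 0.687 to 44.8 ± 7.80 CPM. Gata2 rose from 5.35 ± 0.203 to 50.5 ± 7.68 CPM and the VEGF receptor gene Kdr from 1.303 ± 0.155 to 9.40 ± 0.0873 CPM. Of the 15 tested members of the blood and endothelial progenitor list 7 rose, 1 fell and 7 did not pass, with the same counts risen and fallen adjusted over the list alone, and the list did not pass (camera adjusted p = 0.19).

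All 8 tested trophoblast genes rose, also when adjusted over the list alone (camera adjusted p = 0.00222; adjusted p = 0.275 with an estimated correlation). Cdx2, a trophoblast and posterior transcription factor gene, rose from 0.673 ± 0.485 to 15.2 ± 1.74 CPM. Tpbpa, a spongiotrophoblast marker, had 1 count in EBD5 and 188 in EBD6, a ratio of 108 (95% counting interval 19.2 to 4300). Without EBD5 replicate 3 it had 0 counts in EBD5. Prl3d1, a placental lactogen gene of a family of close copies and so uncertain, had 0 counts in EBD5 and 54 in EBD6. It was at least 10.4-fold higher in EBD6. Outside the lists, Syna, which encodes a syncytin of the placenta, rose 50.9-fold to 18.7 ± 0.788 CPM. All 5 tested surface ectoderm genes rose, also when adjusted over the list alone (camera adjusted p = 0.00536; adjusted p = 0.275 with an estimated correlation), among them Trp63, the gene of the epithelial stem cell factor p63, which rose 27.0-fold to 8.36 ± 0.115 CPM (log2 4.75, or 5.49 without EBD5 replicate 3). Of 12 neuroectoderm genes 11 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00121; adjusted p = 0.42 with an estimated correlation). The forebrain factor gene Six3 (3.29 ± 0.749 to 29.7 ± 1.60 CPM), Zic1 (20.9-fold) and Tubb3 (5.02 ± 1.08 to 34.3 ± 2.45 CPM) were among those that rose.

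T, the Brachyury gene of nascent mesoderm (ENSMUSG00000062327, chromosome 17, 8434423 to 8442496, plus strand), rose from 1.72 ± 0.179 to 26.6 ± 1.80 CPM and the Wnt target Sp5 from 0.886 ± 0.124 to 14.7 ± 1.78 CPM. Eomes fell from 132 ± 2.31 to 65.4 ± 1.84 CPM and Lhx1 from 134 ± 10.7 to 48.4 ± 3.42 CPM. The primitive streak list did not pass (7 of 10 rose and 2 fell, the same adjusted over the list alone; camera adjusted p = 0.313), nor did Wnt response genes (6 of 9 rose and 2 fell, the same adjusted over the list alone; camera adjusted p = 0.249). All 7 BMP response genes rose, also when adjusted over the list alone (camera adjusted p = 0.00282; adjusted p = 0.275 with an estimated correlation). Id3 stood at 10.2 ± 1.01 and 53.5 ± 1.36 CPM and Msx2 at 3.22 ± 0.910 and 30.3 ± 0.741 CPM. All 9 immediate early genes rose, also when adjusted over the list alone (camera adjusted p = 0.000165; adjusted p = 0.362 with an estimated correlation). Junb stood at 8.03 ± 0.995 and 52.6 ± 3.65 CPM and Fos at 7.79 ± 0.460 and 32.7 ± 1.64 CPM. Of 17 imprinted genes 14 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00536; adjusted p = 0.523 with an estimated correlation). The imprinted genes Plagl1 and Cdkn1c rose 7.15-fold and 5.69-fold. Of 11 formative and primed epiblast genes 4 rose and 5 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.353; adjusted p = 0.576 with an estimated correlation). On that list Otx2 (292 ± 7.99 to 94.2 ± 5.61 CPM), Fgf5 (170 ± 5.98 to 57.2 ± 2.37 CPM) and Dnmt3b (426 ± 12.5 to 247 ± 3.41 CPM) fell. The DNA methylation list, which also holds Dnmt3b, did not pass (4 of 8 rose and 3 fell, the same adjusted over the list alone; camera adjusted p = 0.989). Visceral endoderm genes went both ways, 6 higher and 7 lower of 14, with the same counts adjusted over the list alone (camera adjusted p = 0.529). Cubn fell to 406 ± 6.196 CPM, whereas Afp rose to 138 ± 10.7 CPM and Amn, the gene of the partner of cubilin, from 13.0 ± 1.97 to 50.6 ± 8.23 CPM.

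The mitochondrial, ribosomal protein and histone lists were lower in EBD6 than in EBD5 by camera with its preset correlation. None passed with an estimated correlation (camera adjusted p = 0.463, 0.523 and 0.318). All 7 mitochondrially encoded genes fell, also when adjusted over the list alone (camera adjusted p = 0.000165; adjusted p = 0.463 with an estimated correlation), with mt-Co1 at 2287 ± 271 and 160 ± 55.8 CPM. Of 22 ribosomal protein genes 19 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 7.31e-06; adjusted p = 0.523 with an estimated correlation). Of 11 replication histone genes 8 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00303; adjusted p = 0.318 with an estimated correlation). Hist1h1a fell from 42.1 ± 1.17 to 2.28 ± 0.490 CPM. Over all tested genes Zbed6, which lies within another gene, Zc3h11a, so that its counts are uncertain, had 139 ± 15.7 and 3.79 ± 5.36 CPM, with all of its EBD6 counts in replicate 1 and 0 without it. Beside these lists, the share of nuclear ribosomal RNA was 34.0 times and that of mitochondrial ribosomal RNA 62.2 times as high in EBD5 as in EBD6.

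In total 5973 genes were higher and 5383 lower in EBD6 than in EBD5 (edgeR quasi-likelihood, Benjamini-Hochberg), and 2844 and 2473 when tested against a fold of 1.5. Of the 39 lists 10 passed camera, 7 higher and 3 lower, and none with an estimated correlation (smallest adjusted p = 0.275; 5 lists had an unadjusted p under 0.05), while fry gave 32. With 9 separate libraries 6164 genes were higher and 5731 lower, and 11121 of the 11356 calls were shared. With the bins of GC content and length removed, 7615 calls kept their direction and 563 turned. With these bins the log2 change was 3.35 for Hand1, 2.32 for Gata2, 3.07 for Sp5, 3.91 for Cdx2, 1.80 for Tubb3, 1.55 for Cdkn1c, 1.75 for Junb, 1.01 for Amn and -2.71 for mt-Co1. Without the bins these values were 3.96, 3.26, 4.04, 4.53, 2.78, 2.51, 2.72, 1.97 and -3.87.

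Between EBD2 and EBD6, the lists of core pluripotency and of formative and primed epiblast genes were lower in EBD6. Lists of extraembryonic endoderm, trophoblast, primitive streak, lateral plate mesoderm and surface ectoderm genes were higher. These calls are by camera with its preset correlation, and none held with an estimated correlation (camera adjusted p = 0.213 to 0.523). Of 14 core pluripotency genes 11 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00198; adjusted p = 0.409 with an estimated correlation). Tdgf1, the gene of the Nodal co-receptor Cripto, fell from 413 ± 20.2 to 138 ± 19.4 CPM (log2 -1.60 ± 0.09 SE; edgeR quasi-likelihood with Benjamini-Hochberg, adjusted p = 7.9e-08). Sox2 fell from 353 ± 25.9 to 182 ± 20.5 CPM and Dppa2 from 96.7 ± 7.17 to 39.9 ± 5.09 CPM. Pou5f1 fell by 0.51 ± 0.11 SE on the log2 scale, to 186 ± 14.4 CPM, a call that ended when tested against a fold of 1.5. Nanog (185 ± 11.21 and 180 ± 26.1 CPM) and Zfp42 (101 ± 6.25 and 96.8 ± 9.38 CPM) did not pass (edgeR with Benjamini-Hochberg, adjusted p = 0.673 and 0.7). Nor did the lists of naive pluripotency (5 of 12 rose and 4 fell; camera adjusted p = 0.562), which holds both, and of Nodal response (2 of 7 rose and 5 fell; camera adjusted p = 0.179), with the same counts adjusted over the list alone. Of 11 formative and primed epiblast genes 9 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00311; adjusted p = 0.275 with an estimated correlation). Otx2 fell from 247 ± 12.8 to 94.2 ± 5.61 CPM. All 6 two-cell-like genes fell, also when adjusted over the list alone (camera adjusted p = 0.00429; adjusted p = 0.275 with an estimated correlation), and Zscan4e, a member of a near-identical family, was at least 32.5-fold lower. Of 8 DNA methylation genes 7 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.362 with an estimated correlation). Dnmt3a fell from 502 ± 3.29 to 207 ± 8.51 CPM and the 5-methylcytosine oxidase gene Tet2 from 167 ± 5.41 to 58.4 ± 1.17 CPM. Tet3 rose from 33.5 ± 5.24 to 124 ± 14.0 CPM.

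Visceral endoderm genes were higher in EBD6 than in EBD2 (12 of 14 rose and 2 fell, the same adjusted over the list alone; camera adjusted p = 8.52e-05; adjusted p = 0.231 with an estimated correlation), with Afp 294-fold higher. All 11 primitive and parietal endoderm genes rose, also when adjusted over the list alone (camera adjusted p = 1.01e-06; adjusted p = 0.213 with an estimated correlation), and Lama1 reached 373 ± 9.61 CPM. Primitive streak genes rose in 9 of 10 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00318; adjusted p = 0.523 with an estimated correlation), with T 10.4-fold and Lhx1 105-fold higher. The endoderm factor genes Sox17 and Foxa2 stood at 44.7 ± 5.42 and 43.0 ± 2.07 CPM, 86.2-fold and 92.8-fold higher than in EBD2. Without EBD2 replicate 3 the log2 change of Sox17 was 7.43 (6.43 with it). The definitive endoderm list (5 of 7 rose and 2 fell; camera adjusted p = 0.158) and the neuroectoderm list (7 of 12 rose and 0 fell; camera adjusted p = 0.061) did not pass, with the same counts adjusted over the list alone. Lateral plate and extraembryonic mesoderm genes rose in 8 of 9 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00429; adjusted p = 0.275 with an estimated correlation), with Hand1 64.9-fold higher. Cdh5 had 3 counts in EBD2 and 1409 in EBD6, a ratio of 284 (95% counting interval 97.1 to 1380), while its blood and endothelial progenitor list did not pass (8 of 15 rose and 4 fell, or 8 and 5 adjusted over the list alone; camera adjusted p = 0.524). All 5 surface ectoderm genes (camera adjusted p = 0.00685; adjusted p = 0.275 with an estimated correlation) and all 8 trophoblast genes (camera adjusted p = 0.00123; adjusted p = 0.275 with an estimated correlation) rose, also when adjusted over the list alone. Trp63 was at least 49.6-fold and Cdx2 at least 93.8-fold higher, neither having a count in EBD2.

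Of 11 epithelial junction genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00215; adjusted p = 0.362 with an estimated correlation). The keratin genes Krt19 and Krt8 of that list rose 68.1-fold and 13.8-fold. Of 17 imprinted genes 13 rose and 2 fell, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.362 with an estimated correlation). Igf2, a fetal growth factor gene (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816, minus strand, mm10), rose from 18.1 ± 0.904 to 716 ± 95.1 CPM and Grb10 from 28.2 ± 3.52 to 349 ± 26.5 CPM. Of 7 BMP response genes 6 rose and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00539; adjusted p = 0.275 with an estimated correlation). Of 7 FGF and ERK response genes 6 rose as well, the same adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.275 with an estimated correlation). Of 10 p53 target genes 9 rose and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00198; adjusted p = 0.275 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was 3.07-fold and Phlda3 3.87-fold higher. Of 9 immediate early genes 8 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00123; adjusted p = 0.409 with an estimated correlation). Atf3 was 28.3-fold and Egr1 6.51-fold higher. Mitochondrially encoded genes were lower in EBD6 (7 of 7 fell, also when adjusted over the list alone; camera adjusted p = 0.019; adjusted p = 0.583 with an estimated correlation). That call ended with 9 separate libraries (adjusted p = 0.0524 by camera), without EBD2 replicate 2 (0.0648) and with the bins of GC content and length removed (0.363). The 2 pairs counted as 1 sample also differed within themselves in 9 mitochondrial genes each.

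In total 5457 genes were higher and 5228 lower in EBD6 than in EBD2 (edgeR quasi-likelihood, Benjamini-Hochberg), and 2655 and 2263 when tested against a fold of 1.5. Of the 39 lists 17 passed camera, 12 higher and 5 lower, and none with an estimated correlation (smallest adjusted p = 0.213; 10 lists had an unadjusted p under 0.05), while fry gave 32. With 9 separate libraries 5937 genes were higher and 5719 lower, and 10568 of the 10685 calls were shared. With the bins of GC content and length removed, 9603 calls kept their direction and 2 turned.

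**Figure D3:**
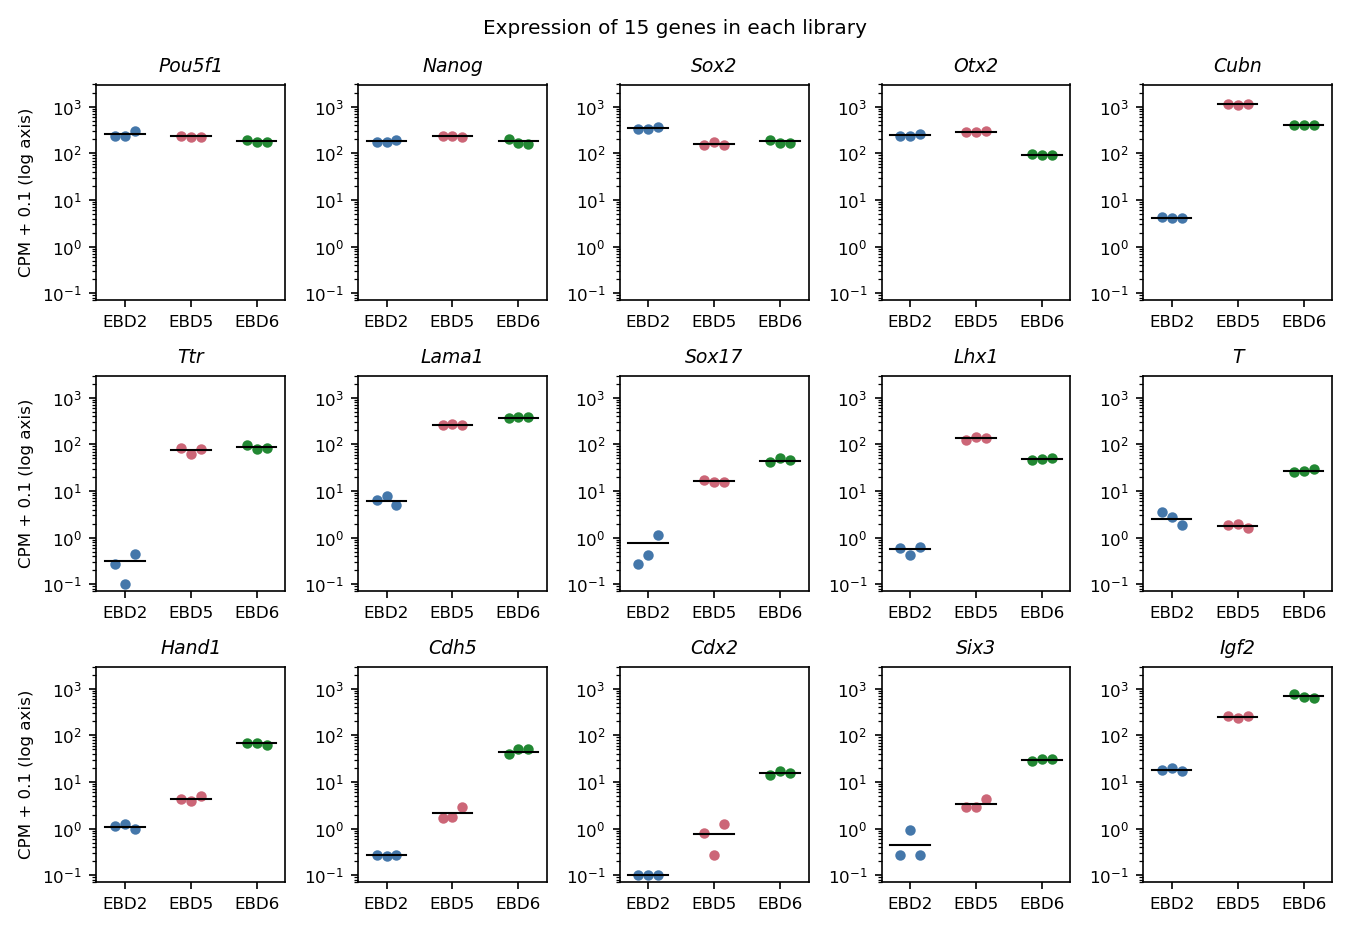
CPM + 0.1 (log axis) of 15 genes in the 9 libraries, with the group mean as a line. Cubn stood at 4.06, 1125 and 406 CPM in EBD2, EBD5 and EBD6, Hand1 at 0.981, 4.30 and 67.0 CPM, and Pou5f1 at 266, 231 and 186 CPM.

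**Figure D4:**
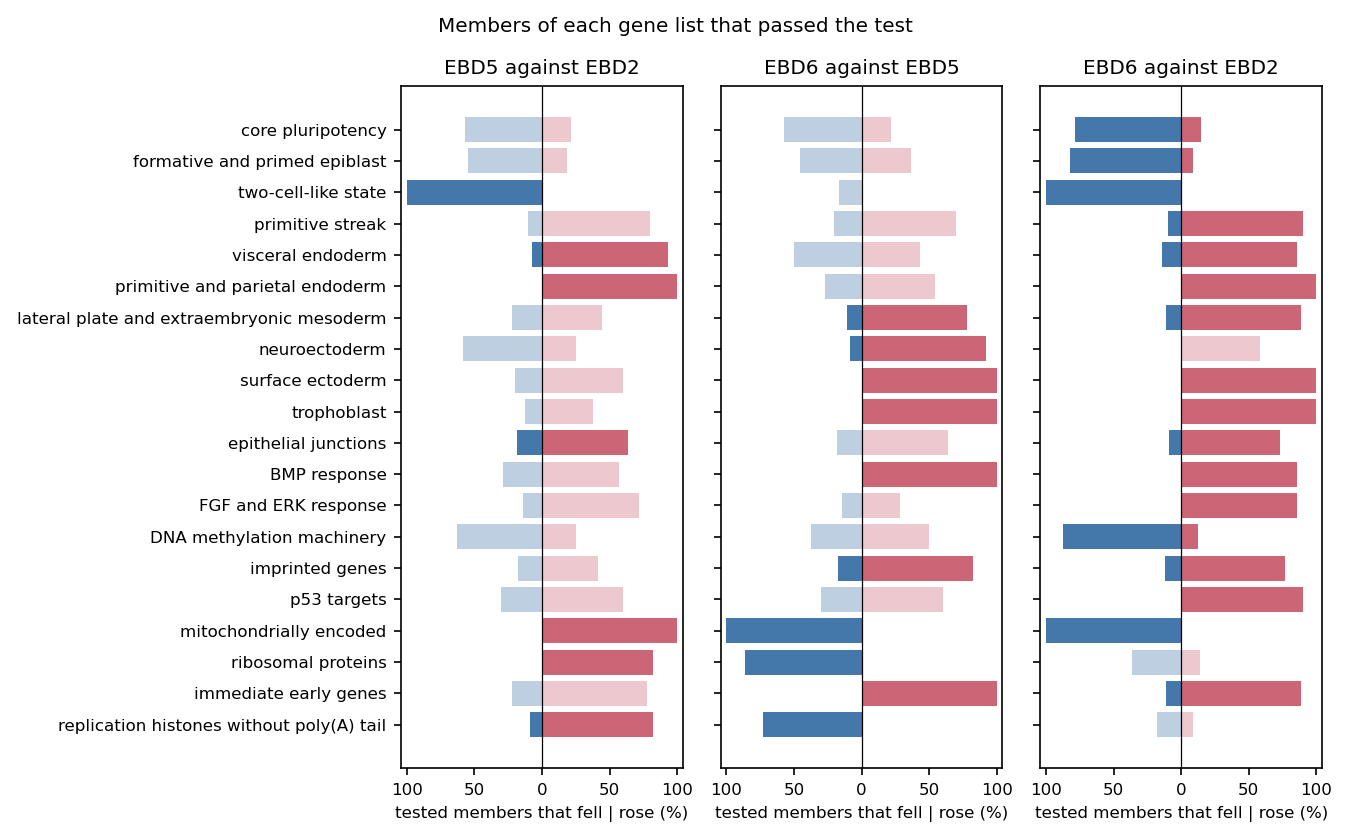
Share of the tested members of 20 gene lists (percent) that fell (left of 0) or rose (right of 0) in each comparison. Dark bars mark lists past camera with the preset correlation, 7, 10 and 17 in the 3 comparisons, none of which passed with an estimated correlation.

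Many genes changed in opposite directions between EBD2 and EBD5 and between EBD5 and EBD6, here called changed back. This means that EBD5 was the highest or lowest group, not that EBD6 was at the EBD2 level. Cubn and Lhx1 were highest in EBD5 and still far higher in EBD6 than in EBD2, and Tubb3 was lowest in EBD5. Of the 5641 genes higher in EBD5 than in EBD2, 3268 were lower in EBD6 than in EBD5, where independent lists of these sizes would share 1878. Of the 5678 lower genes 3223 were higher in EBD6, against 2098 for independent lists. Both comparisons use the same EBD5 libraries, and simulated groups without change gave means of 0.1 and 0.25 such genes. Those groups held no changed genes, so they cannot show how many such genes sharing EBD5 gives among groups that differ. The covariance of the log2 fold changes was -1.43, against -0.029 in the simulation, and the correlation -0.55 against -0.47. The 3 EBD5 libraries were too few to split, and all or part of the excess over independent lists may come from both comparisons holding EBD5.

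Among the gene values named in the text, 34 of 36 in EBD5 against EBD2, 34 of 34 in EBD6 against EBD5 and 28 of 31 in EBD6 against EBD2 passed. The 3 libraries of each group did not overlap for any of those that passed. Chance gives this for 10% of genes with 3 separate libraries against 3. With the pairs counted as 1 sample it gives 20% for EBD5 against either other group and 33.3% for EBD6 against EBD2. Genes picked for large changes that passed would nearly all show it in any case, so the count is no separate evidence.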

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

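The tests on the row MR3 were chosen only after its counts had been seen.

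A row named MR3, which is not an Ensembl gene ID and enters no comparison, held 856, 1258 and 1390 counts in EBD6 replicates 1, 2 and 3. EBD2 libraries held 2, 0 and 1 counts and EBD5 libraries none, which stood out because the signal lay far above the limit of 0.168 CPM (of total counts) that a count of 0 allows over the EBD5 group.

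Lower depth of the EBD2 and EBD5 libraries is argued against, since the lowest rate in EBD6 was 119 CPM. A reference without this row for EBD2 is argued against by the 3 counts that EBD2 libraries held. For EBD5, with 0 counts, a reference without the row cannot be told apart from a sequence that was not there. A sequence present or expressed only in EBD6 cells could give counts in 3 of 3 EBD6 libraries, and it stays open, since the few EBD2 counts neither show nor exclude a trace from other libraries and the sequence behind the row was not used here. No biological explanation was tested.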

How the results depend on the processing

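The settings with 9 separate libraries, EBD5 replicates 1 and 3 as 1 sample, GC content and length bins, protein-coding genes without 3 classes, and thinned EBD6 libraries were chosen after seeing the data. A test against a fold of 1.5 gave 2972 higher and 2634 lower genes in EBD5 against EBD2, 2844 and 2473 in EBD6 against EBD5, and 2655 and 2263 in EBD6 against EBD2, since it asks for a larger change. All other settings run kept each gene count within 1.5 times. Leaving out 1 library gave 5151 to 6071 and 5089 to 6040 genes, 5403 to 6279 and 4877 to 5440, and 4901 to 5848 and 4601 to 5248, higher and lower in the same order. Without EBD2 replicate 3 or EBD6 replicate 1 the group rests on the near-identical pair, which is then assumed to vary like the other groups.

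With EBD5 replicates 1 and 3 as 1 sample, 5699 and 5591, 5865 and 5351, and 5587 and 5309 genes were higher and lower. Of the calls as reported 10741 of 11319, 10774 of 11356 and 10374 of 10685 were shared, and 8, 10 and 18 lists passed.

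With an estimated correlation 0, 0 and 0 lists passed in place of 7, 10 and 17. Without a filter 13 and 17 lists passed in EBD5 against EBD2 and EBD6 against EBD5, and with the GC content and length bins 12 and 16. The cause was not tested. Leaving out 1 library gave 6 to 9, 10 to 11 and 16 to 19 lists.

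Some named genes near 0 changed sign. With the bins, Pou5f1 (0.26) and Zfp42 (-0.03) in EBD5 against EBD2 and Nanog (0.16) and Zfp42 (0.03) in EBD6 against EBD2 did so, as did Zfp42 in EBD5 against EBD2 without EBD5 replicate 2 (-0.18, the highest without 1 library being 0.12) and Nanog in EBD6 against EBD2 without EBD2 replicate 3 (0.01, the lowest without 1 library being -0.17). None of the values with a changed sign passed, and the cause was not tested. Pou5f1 in EBD5 against EBD2 (-0.19) passed without a filter (-0.20). Fitted values of genes with 0 to 3 counts in a group moved as well, and the text gives these as limits or ratios. Tbx6 in EBD6 against EBD2 did not pass as reported (-0.72) and passed with the bins (-0.97), with thinned libraries (-1.20) and without EBD6 replicate 3 (-0.99). Without a filter the median log2 fold change over all genes was 0.239 in EBD6 against EBD5 and 0.19 in EBD6 against EBD2, and changes there are relative to it.

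No sign of pairing by replicate number was seen: same-numbered libraries of different groups had correlations of deviations from -0.08 to 0.05, with 0 of 9 over 0.1. This does not exclude that the numbers mark a shared culture. The replicate block, run on 9 libraries, gave 5821 and 5691, 6071 and 5607, and 5832 and 5620 genes. In that setting 1 list call ended, mitochondrially encoded genes in EBD6 against EBD2 (adjusted p = 0.0507 by camera). The same call ended with 9 libraries without the block (adjusted p = 0.0524 by camera).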

Other observations

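Of the tests in this part, those on poly(A) tails, mitochondrial RNA, GC content and length, and a batch were chosen only after the result had been seen.

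Naive pluripotency genes went both ways. In EBD5 against EBD2 6 of 12 rose and 5 fell, and in EBD6 against EBD5 8 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.901 and 0.0772). Klf2 fell from 116 ± 2.53 (SD) CPM in EBD2 to 32.8 ± 4.43 in EBD5 (log2 -1.82, or -1.06 with the bins of GC content and length removed), and Klf4 rose from 22.5 ± 1.74 in EBD5 to 49.6 ± 4.10 in EBD6. Of 10 germ line genes 7 fell and 2 rose in EBD5 against EBD2, with the same counts adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.0525; adjusted p = 0.362 with an estimated correlation); Dazl, an RNA-binding protein gene of germ cells, fell from 47.5 ± 4.09 to 9.36 ± 0.925 CPM and Mael from 32.6 ± 0.952 to 3.99 ± 0.426 CPM.

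Ttn, the gene of the giant muscle protein titin, fell from 143 ± 10.1 CPM in EBD2 to 26.2 ± 2.38 in EBD5 and 3.82 ± 0.418 in EBD6, while the cardiac muscle list did not pass in EBD5 against EBD2 (2 of 12 rose and 5 fell; camera adjusted p = 0.488) or EBD6 against EBD2 (6 rose and 6 fell; camera adjusted p = 0.772), with the same counts adjusted over the list alone. Of 9 primitive erythroid genes 1 had enough counts to be tested. Of 10 fibroblast and feeder cell genes 5 rose and 2 fell in EBD5 against EBD2, 6 rose and 3 fell in EBD6 against EBD5, and 7 rose and 1 fell in EBD6 against EBD2, with the same counts adjusted over the list alone. The list itself did not pass in any of these comparisons (camera adjusted p = 0.434, 0.433 and 0.178). Lists that did not pass camera in any comparison were those of naive pluripotency, definitive endoderm, presomitic mesoderm, cardiac muscle, blood and endothelial progenitors, germ line, mesenchymal transition, Hox genes, Wnt, Nodal, Notch and retinoic acid response, Polycomb subunits, cell cycle, glycolysis and hypoxia, nuclear oxidative phosphorylation, heat shock, and fibroblasts. Csf1r, the macrophage and trophoblast growth factor receptor gene, rose from 0.490 ± 0.405 CPM in EBD5 to 15.2 ± 4.36 in EBD6 (log2 5.02, or 5.86 without EBD5 replicate 3), and Ctsj, a placental cathepsin gene of a family of close copies and so uncertain, was at least 76.2-fold higher in EBD6.

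The EBD5 libraries held larger shares of ribosomal RNA, mitochondrial, replication histone and processed pseudogene counts. The share of long intergenic non-coding genes was also higher, 2.34 times that of EBD2 and 2.97 times that of EBD6. That class was not part of the tests given here. More mitochondrial RNA of every kind per cell is argued against as the whole cause, since mitochondrial ribosomal RNA rose by 7.11 (EBD6) and 7.73 (EBD2) times the fold of mitochondrial messenger RNA against these groups, and by at least 6.58 times over pairs of libraries. More RNA without a poly(A) tail could account for the histones but not for the ribosomal protein genes, which have tails and whose median was 0.97. In EBD5 against the other groups, replication histone genes outside the fixed list stood 2.48 log2 units above histone genes with tails. The 95% interval of this difference, 1.47 to 3.38, came from resampling genes, which are not independent replicates. It does not measure the spread between samples. Assignment of reads to processed pseudogenes may also have differed. Outside genes named Rpl or Rps and a number, the pseudogene share of parent and pseudogene counts was 2.68% in EBD5. That was 4.79 times the higher of the other groups (0.56% in EBD2). Rpsa and the Rplp genes were not among those left out. A difference in the differentiation itself stays open and untested.

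A total of 6491 genes changed between EBD2 and EBD5 and changed back between EBD5 and EBD6. Here too, changed back means in the opposite direction, whether or not EBD6 was at the EBD2 level. Of these genes 5255 (81%) were protein-coding and outside the RNA classes with larger shares in EBD5. So were 13605 of all 16168 tested genes, which fixed a share over 50% in advance. The test therefore cannot decide whether those classes were the cause. A GC content and length trend of the EBD5 libraries is argued against only as the whole cause. With it removed 3735 (57.5%) still changed and changed back the same way, and the rest did not do so in that way. Of the other tested genes 1257 newly changed and changed back. The bound of more than 50% was set after the counts had been seen. A library or sequencing batch of EBD5 cannot be told apart from the group, because no label gives a batch, and the correlation of GC content with the fold change (0.56 in EBD6 against EBD5) would go with either. A biological difference between the groups, which the labels name only as EBD2, EBD5 and EBD6 differentiation, stays open and untested.

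For each comparison the 6 libraries of the groups, fitted alone as separate samples, allow 10 splits, too few for a share under 0.05. As many genes as in the real split came from 1 of the 10 in each comparison, the real split itself. The real splits gave 11530 genes in EBD5 against EBD2, 11494 in EBD6 against EBD5 and 11270 in EBD6 against EBD2 by edgeR. The highest other split gave 0, with at most 42, 75 and 108 genes at an unadjusted p under 0.05. Every other split put libraries of both groups on each side, so the difference between the groups entered its spread. Few calls there were fixed in advance, so the splits cannot show whether the differences arose by chance.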
